A study of Mus musculus with 11 samples.

How the data were processed

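RNA of inguinal white adipose tissue was extracted with Trizol and made into libraries with the Nextera XT kit, per the labels' protocols, which name no strand. The authors quantified transcripts with Salmon, and edgeR is the other tool named, per the submitters' processing notes, which also name the builds mm10 and GRCm38; versions and the annotation release are not given in the sources used here. Each deposited table, per the file headers, holds 1 library with an estimated count and a TPM value per transcript, beside its length and effective length. The estimated counts need not be whole, because Salmon shares reads among transcripts, and TPM divides by effective length and scales each library to a fixed total, per the file headers and the values.

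The tables list 132288 transcripts. Their identifiers were matched to GENCODE release M21 (GRCm38), 129274 with the version and 131892 (99.7%) without it, which gave 52282 genes. The 396 unmatched transcripts held 0.0985% to 0.144% of a library's reads and were left out. Estimated counts were summed per gene and rounded to whole numbers, and CPM values are the counts scaled to a common library total after TMM normalisation. Symbols and coordinates come from the same annotation. Reads shared by close paralogs are divided by Salmon's model, so members of near-identical families are uncertain, and genes that overlap on opposite strands cannot be told apart where strand is not recorded.

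Groups were taken from the genotype and treatment characteristics. For all 6 WT libraries the title names the opposite treatment; the characteristic was used and grouping by titles was run as an alternative, so that every statement on a WT treatment depends on this choice. KO labels do not conflict. No pair of libraries in a group held identical values, and chi-square statistics per degree of freedom between replicates were 34.5 to 188, so each library counted as 1 sample.

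The main test was edgeR's quasi-likelihood test with robust dispersion in 1 model over all 11 libraries with a mean per group, TMM scaling and the default expression filter by group, which kept 26960 genes. Contrasts were rosiglitazone in WT, rosiglitazone in KO, KO against WT on diet, KO against WT with rosiglitazone, and the interaction. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05, and errors of log2 fold changes are standard errors from the same model. Lists of pathway members and cell type markers, 36 in the test family, were tested with camera at a preset correlation of 0.01, adjusted over the lists. With an estimated correlation camera called 0 lists in each of the 5 contrasts, so that p is given beside the lists; they rest on counts of members and medians. Member counts adjusted over the list alone apply Benjamini and Hochberg within the list. Rptor was compared between genotypes by a two-sided exact permutation test. Groups, tests, contrasts, lists, alternatives and the rule for naming genes were fixed before the data were examined, except for the alternatives said below to be added, the comparison of macrophage with endothelial medians, and the tests of explanations in the closing section, which were written after the design.

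The rule named 12 fixed genes, the 6 highest and 6 lowest log2 fold changes among called genes with an average log2 CPM of at least 1, a symbol that is not a predicted gene and no overlap between the groups' libraries (not asked of the interaction), and up to 4 members with the smallest p in each described list. Some genes that the rule names are not reported here. For a gene with 0 reads in a group, the fold is given against a floor of 3 counts over the group; the floor leaves out the counting error of the higher group, which the lower limit of the exact binomial interval includes, and intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

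Alternatives were RLE and upper-quartile scaling, the DESeq2 Wald test, limma-voom with quality weights, no filter, a filter of 1 CPM in 3 libraries, transcript length offsets, limma-trend on log2(TPM + 1), only the 2 groups compared, the replicate number as a block, WT grouped by titles, other set tests, and each library left out in turn. Added after seeing the data were covariates for B-cell, skeletal muscle and mature adipocyte markers, fits without the 4 libraries with over 0.5% of reads in muscle markers or without the 3 lowest in B-cell markers, protein-coding genes only, Rptor without each library, and Rptor with genotypes permuted within each treatment. The test was checked on simulated counts for the 26960 genes with 200 genes changed, where each gene varied independently of the others. It recovered 79.1% of 4-fold changes for rosiglitazone in WT, 59.7% for rosiglitazone in KO, 62.7% for KO on diet, 77.6% for KO with rosiglitazone and 31.3% for the interaction. At 2-fold it recovered 2.99%, 4.48%, 5.97%, 8.96% and 0% in the same order, and 4 to 9 unchanged genes were called. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.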

Results

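Bulk RNA sequencing of mouse inguinal white adipose tissue, a subcutaneous fat depot in which a lymph node is embedded, gave 11 libraries from C57BL6/J mice aged 16 weeks. The study asked how mTORC1, the growth-regulating kinase complex that needs the subunit Raptor (gene Rptor), and PPARG, the nuclear receptor that drives the adipocyte programme, act together on the transcriptome of this tissue. Raptor was deleted in adipocytes by a Cre recombinase under the adiponectin promoter (KO), and floxed littermates were the controls (WT). For 8 weeks the mice ate a high-fat diet, alone or with the PPARG agonist rosiglitazone at 30 mg per kg per day. There were 3 WT libraries on the diet alone, 3 WT libraries with rosiglitazone, 2 KO libraries on the diet alone and 3 KO libraries with rosiglitazone. For all 6 WT libraries the sample title names the opposite treatment to the treatment characteristic. The WT groups below follow the characteristic, and every direction that involves a WT group holds under that label. The labels do not say whether libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

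Depth was 18910679 and 20163464 estimated reads in the KO libraries on diet alone, and 13035346 to 17167452 in the KO libraries with rosiglitazone. It was 16088059 to 27160069 in the WT libraries labelled diet alone and 18437526 to 40925952 in those labelled rosiglitazone. Genes of ribosomal RNA and the signal recognition particle RNA took from 6.62% of reads, in WT on diet replicate 1, to 28.9%, in KO with rosiglitazone replicate 1. Skeletal muscle markers took 4.53% of reads in KO with rosiglitazone replicate 2, 1.92% in WT on diet replicate 2, 1.80% and 0.887% in WT with rosiglitazone replicates 3 and 2, and at most 0.137% in the other libraries. Summed B-cell markers ranged from 464 CPM (counts scaled to a common library total) in WT with rosiglitazone replicate 2 to 2146 CPM in KO on diet replicate 2. The Y-linked gene Ddx3y averaged 136, 155, 113 and 93.0 CPM in the 4 groups in the order given above, and Xist averaged 1.87, 1.93, 2.44 and 2.15 CPM.

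Rptor (ENSMUSG00000025583.15, GRCm38 chromosome 11, 119602905 to 119899576, plus strand) measured 82.0 ± 9.21 CPM in WT on diet (SD, n = 3) and 118 ± 7.83 CPM in WT with rosiglitazone (SD, n = 3). It measured 63.1 ± 9.25 CPM in KO on diet (SD, n = 2) and 87.5 ± 4.73 CPM in KO with rosiglitazone (SD, n = 3). Across treatments it stood at 77.7 ± 14.5 CPM in KO (SD, n = 5) against 100.2 ± 21.4 CPM in WT (SD, n = 6), a ratio of 0.776 with p = 0.0801 in a two-sided exact permutation test over 462 regroupings, which exchanged libraries across treatments. With genotypes exchanged only within a treatment, a two-sided exact test chosen after seeing the data (200 regroupings), the ratio of the averaged group means was 0.751 with p = 0.01. That p was 0.045 in TPM, and 0.095 in CPM with WT treatments taken from the titles. In TPM, which also divides by transcript length, the ratio was 0.653 with an exact p of 0.0281, and without WT on diet replicate 3 the CPM ratio was 0.737 with an exact p of 0.0476. That was the lowest of 11 leave-one-out ratios in CPM, and the highest was 0.8285, without KO on diet replicate 1. Neither contrast passed the edgeR threshold, at a log2 fold change of -0.38 ± 0.17 on diet (adjusted p = 0.467) and -0.44 ± 0.15 with rosiglitazone (adjusted p = 0.0749). Leaving out each library in turn, the adjusted p for Rptor under rosiglitazone ranged from 0.0389, without WT on diet replicate 1, to 0.255, without KO with rosiglitazone replicate 2. The deletion was made in adipocytes only, per the labels, and the values are over the whole gene and all cells of the tissue. Neither exons nor the adipocyte share of Rptor reads was analysed here.

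**Figure D1:**
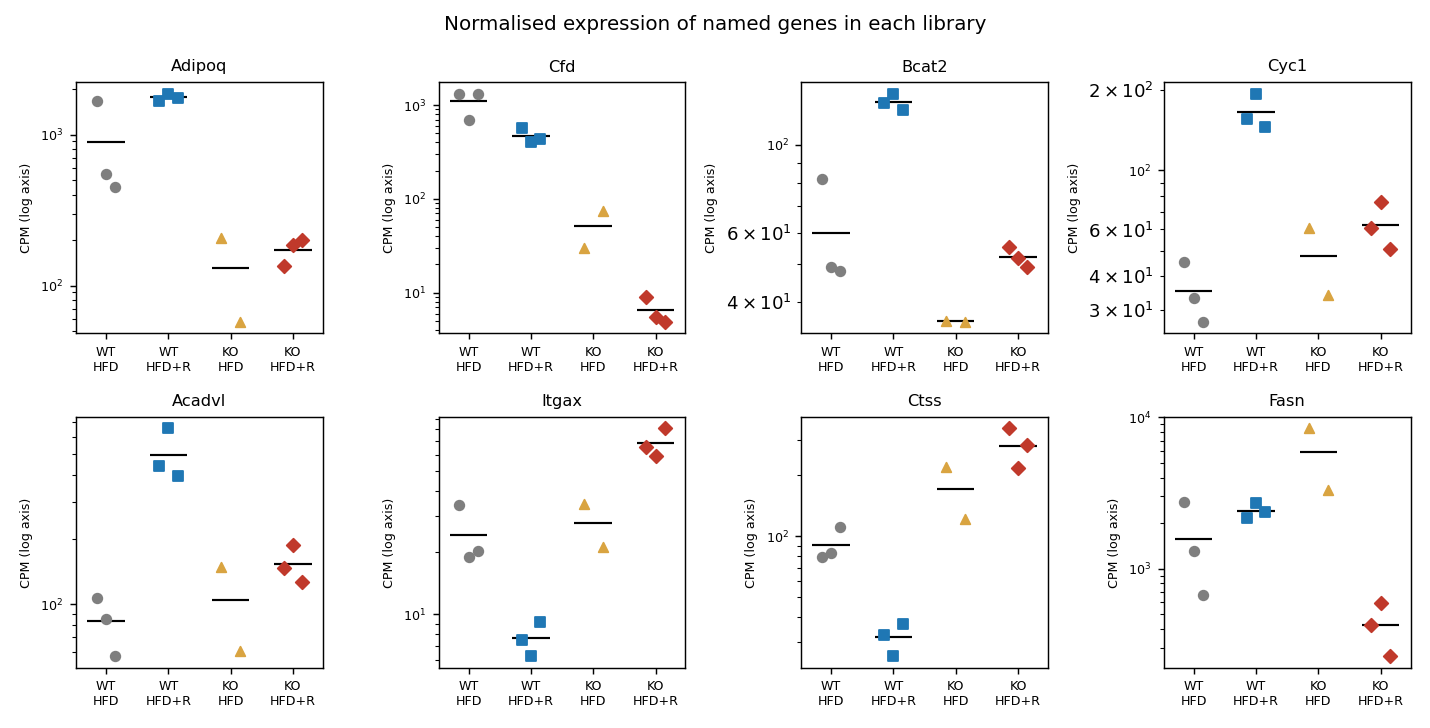
Normalised expression of 8 named genes, where each point is 1 library, the bar is the group mean, and the y axis is CPM on a log scale, with HFD for the diet alone and HFD+R for the diet with rosiglitazone; WT groups follow the treatment characteristic. Adipoq averaged 1766 CPM in WT with rosiglitazone and 173 CPM in KO with rosiglitazone, while Itgax averaged 7.64 and 68.3 CPM in the same groups.

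Rosiglitazone in WT tissue raised transcripts of mitochondrial energy metabolism and lowered several macrophage genes (3 libraries against 3, labels by characteristic). Sptlc3, a subunit of serine palmitoyltransferase that starts sphingolipid synthesis, was 113-fold higher (log2 fold change 6.82 ± 0.58 SE, adjusted p = 0.00453), at 33.3 ± 13.9 CPM against 0.290 ± 0.186 CPM (SD, n = 3 each). Cacng5, a calcium channel gamma subunit, was 133-fold higher (7.06 ± 0.88, adjusted p = 0.0113), and the butyrophilin-like gene Btnl4 was 39.4-fold higher (5.30 ± 0.47, adjusted p = 0.00453). The log2 fold change of Cacng5 ranged from 6.51 to 8.71 with each library left out in turn. Btnl5-ps (4.87), the mitochondrial protein gene Chchd10 (3.89) and the vascular addressin Madcam1 (3.64) also rose. The lowest log2 fold changes belonged to the cytochrome P450 gene Cyp2f2 (-4.88 ± 0.87, adjusted p = 0.0287), the serpins Serpina3n (-4.22) and Serpina1a (-3.92), Tm4sf19 (-3.49), Trabd2b (-2.55) and Lrg1 (-2.44). Counts of Btnl4 and Btnl5-ps, and of the serpins, are uncertain because close paralogs share sequence.

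Oxidative phosphorylation was the group with most changed members: 37 of 59 rose over all genes, 59 of 59 adjusted over the list alone, with a median log2 fold change of 1.503. Cyc1 of complex III (ENSMUSG00000022551.8, GRCm38 chromosome 15, 76343523 to 76346260, plus strand) rose by 2.23 ± 0.28 (adjusted p = 0.0113), Ndufs7 of complex I by 1.42 ± 0.20, Cox5b of complex IV by 1.42 ± 0.20 and Uqcrh of complex III by 1.46 ± 0.21. Fatty acid oxidation had 12 of 24 members higher over all genes and 22 adjusted over the list alone (median 1.89), among them Acadvl, the very-long-chain acyl-CoA dehydrogenase (2.58 ± 0.39), Etfb (2.24), Eci1 (1.89) and Hadha (2.31). In the TCA cycle and pyruvate dehydrogenase list 9 of 23 rose over all genes and 23 adjusted over the list alone (median 1.53), including Sdhb (1.73) and Mdh2 (1.96). For these 3 lists adjusted p = 0.355 with an estimated correlation between genes, and camera with its preset correlation called each. Skeletal muscle, a tissue rich in mitochondria, differed between libraries of both groups as given above, and with its markers as a covariate the oxidative phosphorylation median was 1.465. T and NK cell markers had a median of -1.35 and B-cell markers of -1.68 in this contrast, with 0 of 25 and 0 of 20 members past the edgeR threshold. At an unadjusted p under 0.05 those lists had 0 and 1 lower members, DESeq2 called 0 and 1 lower, and limma-voom called 2 lower in the first and 1 higher and 1 lower in the second.

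Among adipocyte genes, 3 of 24 members of branched-chain amino acid catabolism rose over all genes and 17 adjusted over the list alone (median 0.95, adjusted p = 0.405 with an estimated correlation). These were Bcat2, the mitochondrial aminotransferase of the pathway (1.10 ± 0.20, adjusted p = 0.0306), Echs1 (1.13) and Bckdha (1.70). Known PPARG target genes had 2 of 26 members higher over all genes and 13 adjusted over the list alone (median 1.26, adjusted p = 0.405 with an estimated correlation), namely the lipid droplet gene Plin5 (2.29 ± 0.39) and the fatty acid transporter Slc27a1 (1.63 ± 0.32). At an unadjusted p under 0.05, 17 PPARG targets were higher and 1 lower, while DESeq2 called 13 higher and limma-voom 23. Textbook targets lay on the same side without passing by edgeR: Fabp4 at 1.24 ± 0.44 (adjusted p = 0.181), Pck1 at 1.15 ± 0.41 (0.182), Gk at 1.52 ± 0.65 (0.264), Plin1 at 0.91 ± 0.43 (0.314) and Adipoq at 0.98 ± 0.55 (0.398). Of 22 mature adipocyte markers edgeR called 0, with 2 higher and 1 lower adjusted over the list alone and 7 higher and 2 lower at an unadjusted p under 0.05 (median 0.77, adjusted p = 0.587 with an estimated correlation). DESeq2 called 4 higher and 2 lower in that list, and limma-voom 15 higher and 2 lower. Summed PPARG targets measured 42608, 18639 and 14962 CPM in WT on diet replicates 1, 2 and 3, and 47976 to 57052 CPM with rosiglitazone. Mature adipocyte markers summed to 40098, 14843 and 12119 CPM in those diet libraries, and B-cell markers to 750, 2140 and 1884 CPM. With rosiglitazone the mature adipocyte sums were 35459 to 41455 CPM. Oxidative phosphorylation sums lay at 2157 to 4222 CPM on diet and 8032 to 11076 CPM with rosiglitazone. Brown and beige adipocyte markers had 2 of 25 higher over all genes and 13 higher and 1 lower adjusted over the list alone (median 1.44, adjusted p = 0.405 with an estimated correlation). Otop1 (3.55 ± 0.70) and Cox8b (2.68 ± 0.56) passed, whereas Ucp1, the uncoupling protein of brown fat, stood at 3.34 ± 1.77 (adjusted p = 0.373). With each library left out in turn the Ucp1 value ranged from 2.51 to 13.3. Triglyceride synthesis had 1 of 20 members higher, Gpat4 (adjusted p = 0.0186), and 12 adjusted over the list alone (median 1.14, adjusted p = 0.405 with an estimated correlation). In lipolysis 0 of 16 members passed by edgeR, 5 adjusted over the list alone and 10 at an unadjusted p under 0.05. DESeq2 called 5 and limma-voom 15, and Pnpla2, the first lipase of the pathway, stood at 1.68 ± 0.39 (adjusted p = 0.0592). The lipolysis median was 1.03 (adjusted p = 0.405 with an estimated correlation).

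Macrophage markers had 5 of 26 members lower over all genes and 10 adjusted over the list alone (median -0.84, adjusted p = 0.462 with an estimated correlation). Itgax, the integrin CD11c of adipose tissue macrophages (ENSMUSG00000030789.9, GRCm38 chromosome 7, 128129547 to 128150657, plus strand), fell by 1.68 on the log2 scale (SE 0.28, adjusted p = 0.0246), Mpeg1 by 1.57, the lysosomal protease Ctss by 1.52 and Cd84 by 1.23. The pericyte genes Rgs5 (-2.14) and Kcnj8 (-2.10) were the 2 of 14 pericyte and smooth muscle markers to fall, with 5 adjusted over the list alone (median -0.94, adjusted p = 0.406 with an estimated correlation). B-cell and T-cell markers had the medians of -1.68 and -1.35 given above without a call (adjusted p = 0.645 and 0.661 with an estimated correlation), and T and NK sums overlapped between the groups, at 33.6 to 281 CPM with rosiglitazone and 58.1 to 729 CPM without. In all, edgeR called 578 of 26960 genes, 418 higher and 160 lower, and 4700 genes had an unadjusted p under 0.05. The count leaned on single libraries in every case. It was 213, 225 and 182 without KO with rosiglitazone replicates 1, 2 and 3, and 1063 and 1080 without KO on diet replicates 1 and 2, since all libraries share the estimate of spread. It was 39, 18 and 67 without WT with rosiglitazone replicates 1, 2 and 3, and 2779, 27 and 30 without WT on diet replicates 1, 2 and 3. Of 36 called genes named for this contrast, Sptlc3 and Btnl4 passed without each library and 34 missed the threshold without at least 1. Without the 4 libraries richest in muscle reads edgeR called 0 genes with 958 at an unadjusted p under 0.05 and 1 WT library left with rosiglitazone. The fit without the 3 libraries lowest in B-cell markers left 1 KO library on diet, so its count is left out.

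**Figure D2:**
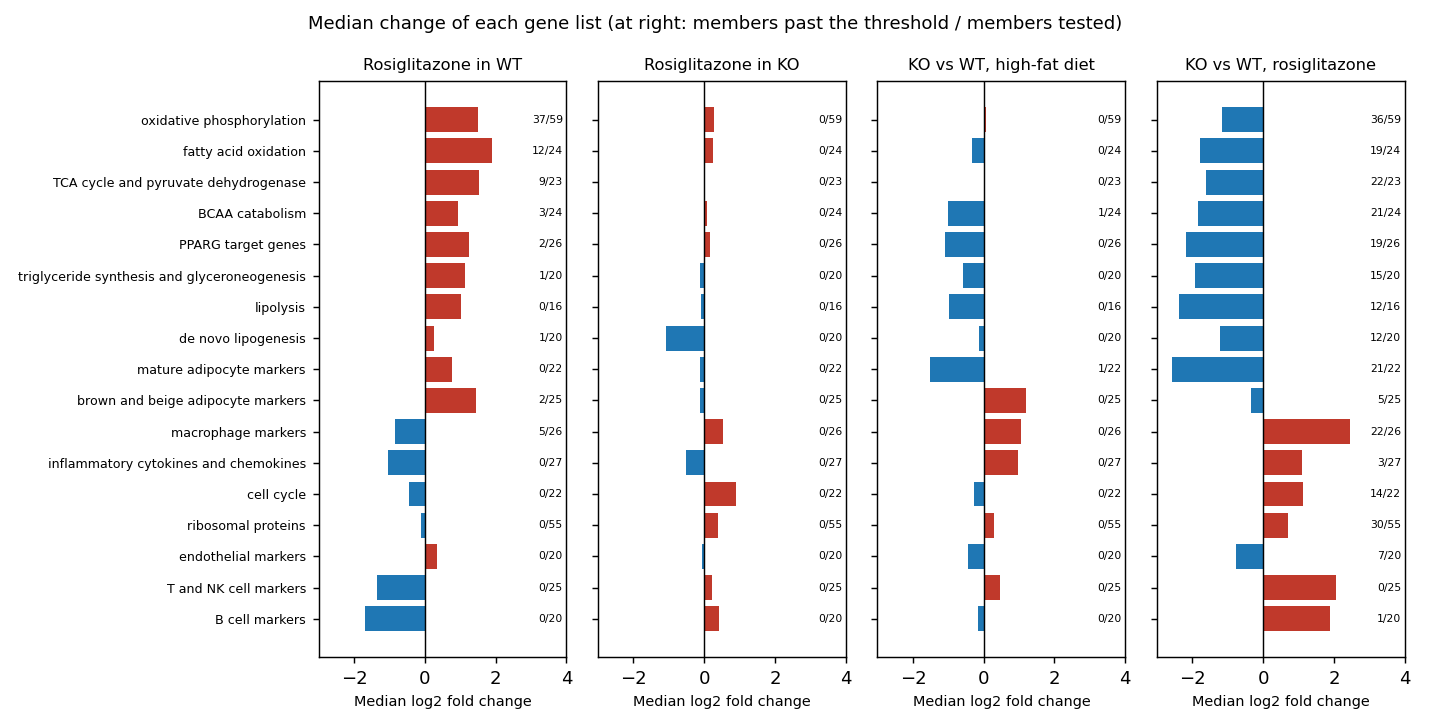
Median log2 fold change of 17 gene lists in the 4 comparisons between groups, where red bars are medians above 0, blue bars medians below 0, and the numbers at the right give members past the edgeR threshold over members tested; WT groups follow the treatment characteristic. Oxidative phosphorylation had a median of 1.503 with rosiglitazone in WT and of -1.15 in KO against WT under rosiglitazone; camera with an estimated correlation called none of the lists.

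Rosiglitazone in KO tissue, labelled as Raptor-deleted in adipocytes, changed 4 genes (3 libraries against 2, edgeR), with 2254 genes at an unadjusted p under 0.05. Btnl4 rose by 6.55 ± 0.66 on the log2 scale (adjusted p = 0.0219), from 0.0799 ± 0.113 CPM (SD, n = 2) to 8.67 ± 0.466 CPM (SD, n = 3). That log2 fold change ranged from 5.71 to 10.5 with each library left out in turn. C77080 rose by 1.95 ± 0.23 (adjusted p = 0.0491), from 17.9 ± 5.14 to 69.1 ± 2.48 CPM. The histone gene Hist1h2ap had 0 reads in KO on diet and 387 in KO with rosiglitazone, at least 129-fold higher against a floor of 3 counts over the group, with 104 as the lower limit of the counting interval of the ratio. It is uncertain because histone genes exist in near-identical copies. Slc2a5, the fructose transporter GLUT5, had 408 reads in KO on diet and 2 in KO with rosiglitazone, a ratio of 204 with a counting interval of 56.2 to 1692 (adjusted p = 0.0298). Slc2a5 fell outside the naming rule and was chosen after its values were seen. Of the 4 genes, Hist1h2ap alone passed without each library in turn. Across the 11 leave-one-out fits the adjusted p ranged from 0.00912 to 0.116 for Btnl4, 0.0269 to 0.154 for C77080 and 0.00912 to 0.144 for Slc2a5.

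No list member in this contrast passed over all genes by edgeR in the lists described next. Cell cycle genes had 15 of 22 members higher adjusted over the list alone, also 15 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom (median 0.90, adjusted p = 0.505 with an estimated correlation). Ccnb2 stood at 1.26 ± 0.25 (adjusted p = 0.166), the mitotic kinesin Kif11 at 1.03 ± 0.23 (0.224) and Rrm2 at 1.46 ± 0.32 (0.225). Fatty acid synthesis had 9 of 20 members lower adjusted over the list alone, 10 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom (median -1.07, adjusted p = 0.725 with an estimated correlation). Fasn, the fatty acid synthase, stood at -3.78 ± 0.63 (adjusted p = 0.109), Acaca at -3.06 ± 0.48, Acly at -2.43 ± 0.37 and Thrsp at -2.99 ± 0.43 (adjusted p = 0.0787 for these 3). Fasn measured 8435 and 3324 CPM in the 2 KO libraries on diet and 263 to 593 CPM in the 3 with rosiglitazone. Cfd, the adipokine adipsin, stood at -2.98 ± 0.45 (adjusted p = 0.0787), and the macrophage genes Trem2 at 1.96 ± 0.40 (0.177) and Itgax at 1.29 ± 0.32 (0.269).

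The 2 KO libraries on diet differed from each other in cell content: T and NK cell markers summed to 66.0 CPM in replicate 1 and 1161 CPM in replicate 2, and B-cell markers to 472 and 2146 CPM. Mature adipocyte markers summed to 8145 and 2612 CPM and macrophage markers to 5298 and 1926 CPM in the same libraries. In the KO libraries with rosiglitazone the T and NK sums were 696 to 804 CPM. Skeletal muscle markers had a median of 5.96 in this contrast (adjusted p = 0.887 with an estimated correlation), and of -0.44 without KO with rosiglitazone replicate 2. Counts of called genes without KO on diet replicate 1 or 2 are left out, as each fit left 1 KO library on diet. The count was 1 without KO with rosiglitazone replicate 1, 2 or 3 or WT with rosiglitazone replicate 2 or 3, and it was 21 without WT on diet replicate 1, and 2 without WT on diet replicate 2. DESeq2 called 364 genes, and limma-voom called 0 with 1153 at an unadjusted p under 0.05. The fit without the 3 libraries lowest in B-cell markers also left 1 KO library on diet, so its count is left out. On the TPM scale 254 genes passed, 9 higher and 245 lower, where the median of all genes moved by -0.588.

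On the diet alone, 1 of 22 mature adipocyte markers, Cfd, and 0 of 26 PPARG target genes passed over all genes between KO and WT tissue (2 libraries against 3, edgeR). At an unadjusted p under 0.05, 11 of the PPARG targets were lower and 2 higher, with 5 and 2 by DESeq2 and 0 by limma-voom. Cfd fell by 4.43 on the log2 scale (SE 0.54, adjusted p = 0.0225), from 1116 ± 359 CPM in WT (SD, n = 3) to 51.7 ± 30.8 CPM in KO (SD, n = 2). Acsm5, a medium-chain acyl-CoA synthetase, fell by 4.67, the pantetheinase Vnn1 by 4.46, the GTPase Rasd1 by 5.46 and the GABA transporter Slc6a13 by 4.29. Higher in KO were Aspg (3.71 ± 0.46, adjusted p = 0.0225), Sorcs2 (3.46), the parathyroid hormone receptor Pth1r (2.68) and Cd209g (2.51). Hist1h2ap had 0 reads in KO on diet and 311 in WT on diet, at least 75.1-fold lower against the same floor (lower counting limit 60.7). The fixed adipocyte genes did not pass: Adipoq stood at -2.76 ± 0.69 (adjusted p = 0.178), Pck1 at -2.36 ± 0.49 (0.124), Lep at -3.38 ± 1.05 (0.283) and Plin1 at -1.49 ± 0.50 (0.322).

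Of 22 mature adipocyte markers, 1 fell over all genes, Cfd, and 14 adjusted over the list alone (median -1.51, adjusted p = 0.455 with an estimated correlation). Rbp4 at -4.38 ± 0.74 (adjusted p = 0.0737) and Car3 at -3.76 ± 0.69 (0.0859) missed the threshold. In branched-chain amino acid catabolism 1 of 24 members fell, Ivd (-1.86 ± 0.26, adjusted p = 0.0381), and 14 adjusted over the list alone (median -1.02, adjusted p = 0.455 with an estimated correlation). Mccc2 stood at -1.76 ± 0.35 (0.105). Macrophage markers had 18 of 26 members higher adjusted over the list alone and 0 over all genes by edgeR, with 19 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (median 1.06, adjusted p = 0.477 with an estimated correlation). Among them Cd163 stood at 1.33 ± 0.37, Fcer1g at 1.26 ± 0.39 and C1qb at 1.41 ± 0.43. The macrophage median was 0.09 without KO on diet replicate 1 and 1.64 without replicate 2, and the adipocyte median was -2.44 and -0.97. The skeletal muscle markers had a median of -4.64 in this contrast and B-cell markers of -0.17 (adjusted p = 0.510 and 0.948 with an estimated correlation).

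In fatty acid synthesis the members split, 7 of 20 higher and 5 lower adjusted over the list alone and 0 over all genes by edgeR, with the same 7 and 5 at an unadjusted p under 0.05. DESeq2 called 5 higher and 3 lower and limma-voom 0. Acly stood at 2.08 ± 0.37 (adjusted p = 0.0807), Acaca at 2.01 ± 0.47 (0.163) and Fasn at 1.90 ± 0.60 (0.290), while the desaturase Scd1 stood at -3.43 ± 0.73 (0.134). The list had a median of -0.12 and a mean of -0.01 (adjusted p = 0.948 with an estimated correlation), camera placed it upward without a call, and its median was 0.06 on the TPM scale and 0.13 by limma-voom. Brown and beige adipocyte markers had 0 of 25 past the threshold over all genes by edgeR, 3 higher and 1 lower adjusted over the list alone (median 1.19, adjusted p = 0.510 with an estimated correlation), and the median was -0.11 with WT grouped by titles and 0.21 without KO on diet replicate 1. In that list 10 were higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 4 higher and 1 lower and limma-voom 0. Acot11 stood at 2.77 ± 0.44 (0.0538) and Cidea at 3.88 ± 0.89 (0.167). In all, edgeR called 37 genes, 7 higher and 30 lower, with 2829 at an unadjusted p under 0.05. Left-out libraries moved the count to 12, 18 and 18 (KO with rosiglitazone replicates 1, 2 and 3). It was 2, 9 and 5 without WT with rosiglitazone replicates 1, 2 and 3. Without WT on diet replicates 1 and 3 it was 75 and 81. Counts without KO on diet replicate 1 or 2 are left out, as each fit left 1 KO library on diet. Of 11 called genes named, 10 missed the threshold without at least 1 library, and Cfd ranged from an adjusted p of 0.0139 to 0.0598. The calls ended with only the 2 groups compared (0 genes, 1404 at an unadjusted p under 0.05) and nearly so with the replicate block (1) and limma-voom (6). The mature adipocyte covariate gave 4256 genes, 2677 higher and 1579 lower. Grouped by titles, the same contrast called 2886 genes, and without the 4 libraries richest in muscle it called 0 with 1492 at an unadjusted p under 0.05.

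**Figure D3:**
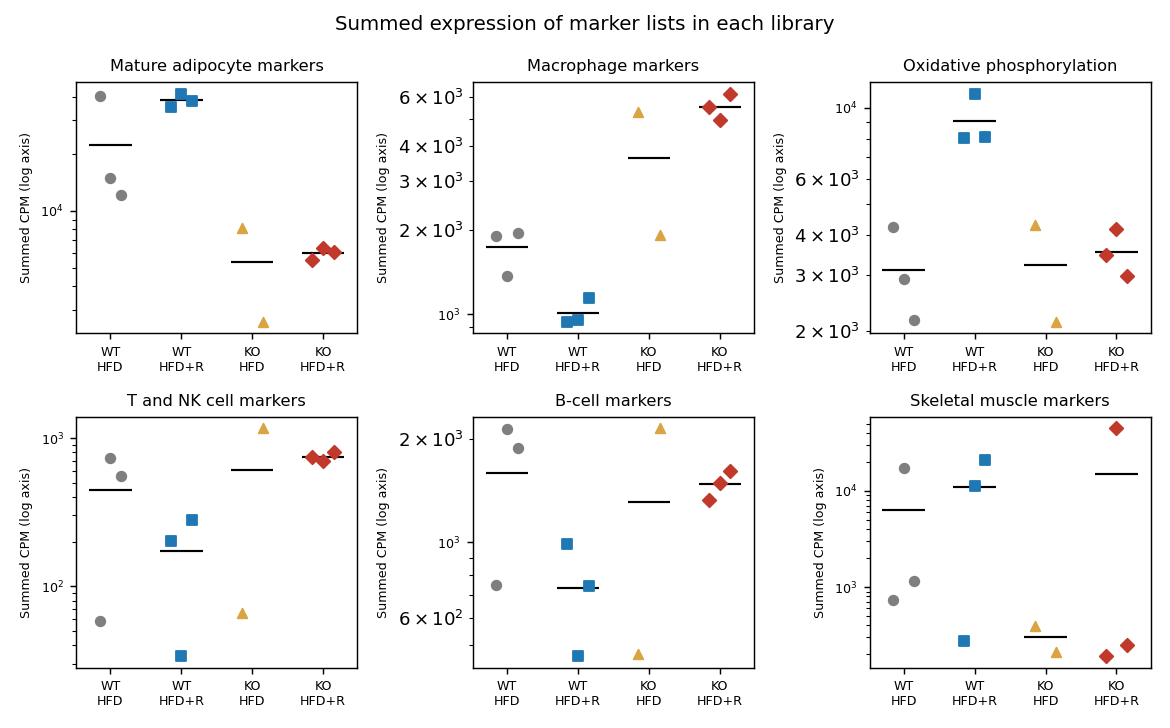
Summed expression of 6 gene lists, where each point is 1 library, the bar is the group mean, and the y axis is the sum of CPM over the list's members on a log scale, with HFD for the diet alone and HFD+R for the diet with rosiglitazone; WT groups follow the treatment characteristic. Macrophage markers summed to 942 to 1143 CPM in WT with rosiglitazone and to 4949 to 6152 CPM in KO with rosiglitazone.

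Under rosiglitazone, KO tissue had broadly lower adipocyte transcripts and higher macrophage transcripts than WT (3 libraries against 3, WT labels by characteristic). RNA composition also separated these groups: ribosomal and signal recognition particle RNA genes took 15.8% to 28.9% of reads in KO and 9.50% to 12.2% in WT. Protein-coding genes took 59.0% to 71.5% and 77.6% to 78.1%. Adipoq, which encodes adiponectin (ENSMUSG00000022878.5, GRCm38 chromosome 16, 23146536 to 23158028, plus strand), was 10.2-fold lower (-3.35 ± 0.60, adjusted p = 0.00707), at 173 ± 34.7 CPM in KO against 1766 ± 94.2 CPM in WT (SD, n = 3 each). Cfd fell by 6.17 on the log2 scale (SE 0.49, adjusted p = 0.000306), Vnn1 by 6.26, Acsm5 by 5.50 and the imprinted gene Mest by 5.29. Klf14 had 0 reads in KO and 169 in WT, at least 33.6-fold lower against the floor (lower counting limit 27.0). Adam3 had 2 reads against 357, a ratio of 106 with a counting interval of 29.3 to 883. Tm4sf19 was 122-fold higher in KO (6.93 ± 0.72, adjusted p = 0.000777), followed by Nptx1 (6.23), the lysosomal glycoprotein Gpnmb of lipid-laden macrophages (6.01 ± 0.73), osteopontin Spp1 (5.76 ± 1.60, adjusted p = 0.0414), the proton pump subunit Atp6v0d2 (5.35) and Myh15 (5.17).

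Of 22 mature adipocyte markers 21 fell over all genes and 22 adjusted over the list alone (median -2.57, adjusted p = 0.306 with an estimated correlation). Nrg4 (-3.17 ± 0.37), the beta-3 adrenergic receptor Adrb3 (-2.69 ± 0.33), Retn (-3.59 ± 0.48) and Plin1 (-2.39 ± 0.45, adjusted p = 0.00862) were among them. Of 26 PPARG target genes 18 fell and 1 rose over all genes, 21 and 1 adjusted over the list alone (median -2.16, adjusted p = 0.306 with an estimated correlation). Pck1 stood at -3.42 ± 0.44 (adjusted p = 0.00176), Fabp4 at -2.02 ± 0.45 (0.0162), Plin4 at -2.76 and Pparg itself at -1.67 ± 0.46 (0.0373), while Cd36 at -1.52 ± 0.60 did not pass (0.117). In lipolysis 12 of 16 fell, 15 adjusted over the list alone (median -2.38), with Pde3b at -2.46. In triglyceride synthesis 14 fell and 1 rose of 20, 15 and 2 adjusted over the list alone (median -1.93), with Gpat4 at -1.89 and Dgat2 at -3.18. Of 25 adipokines and secreted factors 13 fell and 1 rose, 15 and 2 adjusted over the list alone (median -1.60), and leptin, Lep, stood at -3.28 ± 0.89 (adjusted p = 0.0353). For these 3 lists adjusted p = 0.306 with an estimated correlation. Pparg and Lep each lost the call without any 1 of the 6 libraries compared, and their adjusted p ranged from 0.00731 to 0.124 and from 0.0113 to 0.123 over the 11 leave-one-out fits. Fabp4 lost it without KO replicate 1, 2 or 3 or WT replicate 2, with a range of 0.00298 to 0.0737. With the mature adipocyte covariate, which removes these changes by construction, the medians turned to 0.78 for PPARG targets, 0.31 for lipolysis and 0.34 for triglyceride synthesis.

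Mitochondrial lists were lower as well, but not with the mature adipocyte covariate, chosen after seeing the data, which removes the adipocyte level by construction. With it the medians were 0.52 for oxidative phosphorylation, 0.57 for fatty acid oxidation, 0.57 for the TCA cycle and 0.03 for branched-chain amino acid catabolism. Pdhx stood at 0.12 and Sdha at 0.0066. In branched-chain amino acid catabolism 21 of 24 members fell, 22 adjusted over the list alone (median -1.84), led by Hibch (-2.37 ± 0.28), Mccc2 (-2.45 ± 0.31) and Ivd (-1.84 ± 0.23), with Bcat2 at -1.30 ± 0.20 (adjusted p = 0.0043). In the TCA cycle and pyruvate dehydrogenase list 22 of 23 fell, 23 adjusted over the list alone (median -1.60), including Pdhx (-1.71) and Sdha (-1.68). Fatty acid oxidation had 19 of 24 lower, 21 adjusted over the list alone (median -1.78), among them Eci1 (-2.08). Oxidative phosphorylation had 36 of 59 lower, 57 adjusted over the list alone (median -1.15), among them Ndufb3 (-2.0007), Ndufs3 (-1.44) and Cox5b (-1.12). For these 4 lists adjusted p = 0.306 with an estimated correlation. Fatty acid synthesis had 12 of 20 lower, 14 adjusted over the list alone (median -1.21, adjusted p = 0.316 with an estimated correlation), with Fasn at -2.50 ± 0.57 (adjusted p = 0.0189), the citrate carrier Slc25a1 at -2.71 and Scd1 at -3.77. Insulin signalling had 9 lower and 2 higher of 19, 15 and 4 adjusted over the list alone (median -0.86, adjusted p = 0.306 with an estimated correlation), with Akt2 at -2.05 and the insulin receptor Insr at -1.37.

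Macrophage markers rose in 22 of 26 cases over all genes, 24 adjusted over the list alone (median 2.46, adjusted p = 0.306 with an estimated correlation). Ctss rose by 3.14 ± 0.29 (adjusted p = 0.000547), Itgax by 3.16 ± 0.30, Cd84 by 2.47 ± 0.24 and the lipid sensor Trem2 by 3.78 ± 0.37. Cell cycle genes rose in 14 of 22 cases, 17 adjusted over the list alone (median 1.13, adjusted p = 0.306 with an estimated correlation), including Mcm6 (1.35 ± 0.20) and Pcna (0.96 ± 0.15). Of 20 endothelial markers 7 fell, 13 adjusted over the list alone (median -0.77, adjusted p = 0.461 with an estimated correlation), Robo4 (-1.31 ± 0.28) and Cldn5 (-1.53 ± 0.34) among them. Lymphocyte markers had a median of 2.06 for T and NK cells (adjusted p = 0.598 with an estimated correlation) and 1.90 for B cells (0.602). Of the T and NK list edgeR called 0 of 25 members, with 1 at an unadjusted p under 0.05, 2 by DESeq2 and 4 by limma-voom, and of the B-cell list 1 of 20, lower. The sums of both lists nonetheless did not overlap between the groups. T and NK markers summed to 696 to 804 CPM in KO and 33.6 to 281 CPM in WT, and B-cell markers to 1329 to 1614 and 464 to 988 CPM.

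EdgeR called 4037 genes in this contrast, 1476 higher and 2561 lower, with 8444 at an unadjusted p under 0.05. The count was 1645, 2407 and 1500 without KO with rosiglitazone replicates 1, 2 and 3, and 2105, 1498 and 2240 without WT with rosiglitazone replicates 1, 2 and 3. Of 63 called genes named for this contrast 51 passed without each library in turn. Without the 4 libraries richest in muscle edgeR called 0 genes with 2538 at an unadjusted p under 0.05, where 1 WT library with rosiglitazone was left, and the medians were -2.48 for adipocyte and 2.56 for macrophage markers. On the TPM scale 4078 genes passed, 225 higher and 3853 lower, with the median of all genes moved by -0.354. With the mature adipocyte covariate 2522 passed, 1842 higher and 680 lower, of which 475 were among the 4037, 383 with the same sign. Grouped by titles the contrast called 624 genes, with an oxidative phosphorylation median of 0.29 in place of -1.15.

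The genotype difference had the same sign on diet for 3476 of the 4037 genes called under rosiglitazone (86.1%), and 32 of the 37 genes called on diet had the same sign under rosiglitazone (86.5%). The 2 contrasts share no library. Called lower in both were 27 genes, where independent lists of those sizes would share 2.85, and called higher in both were 3, against 0.383. Cfd, Acsm5, Vnn1 and Ivd passed in both, each lower in KO.

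Whether the drug acted differently in KO than in WT was tested by the interaction (edgeR). Of the 28 genes called, the log2 fold change with the drug was higher in KO than in WT for 23 and lower for 5. At an unadjusted p under 0.05 there were 2840 genes. Itgax, 1 of 26 macrophage markers to pass, differed by 2.98 ± 0.43 on the log2 scale (adjusted p = 0.0448). It measured 24.4 ± 8.32 and 7.64 ± 1.49 CPM in WT without and with the drug (SD, n = 3 each), and 27.8 ± 9.22 and 68.3 ± 11.01 CPM in KO (SD, n = 2 and 3). The carboxypeptidase Cpe differed by 3.05 ± 0.37 (adjusted p = 0.0319) and the sodium-activated potassium channel Kcnt1 by -3.67 ± 0.42 (adjusted p = 0.0319). Nat8l, which makes N-acetylaspartate, differed by -2.88 ± 0.37 (adjusted p = 0.0369). The lipogenic genes Acaca at -4.24 ± 0.64 (0.051) and Fasn at -4.39 ± 0.83 (0.0981) did not pass. Each of the 8 called genes named for the interaction lost its call without at least 1 library, with Itgax between an adjusted p of 0.0323 and 0.178. The count was 4, 4 and 1 without KO with rosiglitazone replicates 1, 2 and 3. It was 2, 1 and 1 without WT with rosiglitazone replicates 1, 2 and 3. Without WT on diet replicates 1, 2 and 3 it was 113, 3 and 3, the first with 56 higher and 57 lower. Counts without KO on diet replicate 1 or 2 are left out, as each fit left 1 KO library on diet. With the replicate block 1 gene was called, and 1 with the skeletal muscle covariate. DESeq2 called 531 genes, limma-voom 61 (31 higher and 30 lower) and edgeR with titles as WT labels 154.

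By list, oxidative phosphorylation had an interaction median of -1.25, with 0 of 59 members past the edgeR threshold over all genes, 41 lower adjusted over the list alone, 45 lower at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom. Cyc1 stood at -1.83 ± 0.40 (adjusted p = 0.141). The TCA cycle and pyruvate dehydrogenase list had a median of -1.62, with 0 of 23 past the threshold over all genes, 22 lower adjusted over the list alone and at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma-voom, and Pdha1 at -2.75 ± 0.63 (adjusted p = 0.159). Cell cycle genes had a median of 1.47, with 0 of 22 over all genes, 15 higher adjusted over the list alone, 16 at an unadjusted p under 0.05, 11 by DESeq2 and 0 by limma-voom, and Kif11 at 1.59 ± 0.30 (adjusted p = 0.0981). Macrophage markers had a median of 1.65, with 12 higher and 1 lower adjusted over the list alone, Ctss at 2.23 ± 0.42 and Trem2 at 2.73 ± 0.52 (adjusted p = 0.0981 for both). With an estimated correlation adjusted p = 0.520 for all 4 of these lists. B-cell markers had an interaction median of 2.09, T and NK cell markers of 1.60 and skeletal muscle markers of 5.21, each without a call over all genes by edgeR, DESeq2 or limma-voom (0 at an unadjusted p under 0.05; adjusted p = 0.595, 0.595 and 0.737 with an estimated correlation). The last median was -1.20 without KO with rosiglitazone replicate 2. With WT grouped by titles the medians turned, to 1.74 for oxidative phosphorylation, 1.55 for the TCA cycle and -0.19 for macrophage markers.

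Across all 26960 tested genes the drug's log2 fold changes in WT and in KO correlated at a Pearson r of 0.0986 and a Spearman rho of 0.0563, with a jackknife SE of 0.268 for r over the libraries. Genes are not independent replicates. Over the 578 genes called in WT r was 0.269, and 393 had the same sign in KO (68.0%). These were 315 of 418 among those higher and 78 of 160 among those lower. Over all tested genes 14174 of 26960 had the same sign (52.57%). Btnl4 was higher with the drug in both genotypes, the 1 gene called in both, where 0.0465 would be shared by independent lists. Sptlc3 measured 0 CPM in both KO libraries on diet and 4.59 ± 1.58 CPM in KO with rosiglitazone (SD, n = 3), and Cacng5 measured 0.246 ± 0.348 and 2.35 ± 0.261 CPM in the same groups. Without KO on diet replicate 2 the correlation was -0.127, and without WT on diet replicate 2 it was 0.221.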

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

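The comparison of macrophage with endothelial markers and the marker covariates were chosen after the data had been seen. The bounds for the covariate tests were set before their results were seen. In the covariate tests below, the spread beside a list median is the median standard error of the list's single genes. It is not a standard error of the median and leaves out the correlation between genes.

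The effect of rosiglitazone passed the edgeR interaction test between KO and WT, with all 11 libraries and no block, for Nptx1 (difference of log2 fold changes 5.42), Plxdc1 (3.32), Cpe (3.05), Itgax (2.98), Pianp (2.97), Kcnt1 (-3.67), Nat8l (-2.88) and Olfr1033 (-2.16). Each of these 8 genes lost the call without at least 1 library, and of the 28 genes called 1 was also called with the replicate block and 1 with the skeletal muscle covariate. By camera with its preset correlation the effect also differed for oxidative phosphorylation (median difference -1.25), the TCA cycle and pyruvate dehydrogenase (-1.62), the cell cycle (1.47), macrophage markers (1.65), fatty acid oxidation (-1.58) and fatty acid synthesis (-1.22). For these 6 lists adjusted p = 0.520 with an estimated correlation.

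Oxidative phosphorylation transcripts were higher with rosiglitazone in WT, at a median of 1.503. With B-cell markers as a covariate the median was 1.33 (spread 0.195), above the bound of 1 set for it. By that bound a different amount of lymph node tissue is argued against as the whole cause, with no error of the median estimated. Skeletal muscle in some libraries is argued against in the same way, at a median of 1.465 (spread 0.315) with its markers as a covariate. A higher share of adipocytes stays open: with adipocyte markers as a covariate the median was 1.09 (spread 0.186), within that spread of the bound. Of the 10 splits of these 6 libraries into 3 and 3, only 1, the real one, called as many as 578 genes and the highest other called 1, which is too few splits for a share under 0.05. An effect of the drug, which the design names, stays open under the WT labels used, and no test here told it apart from a higher share of adipocytes.

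Adipocyte transcripts were lower and macrophage transcripts higher in KO than in WT under rosiglitazone. With the B-cell covariate the adipocyte median was -2.10 (spread 0.284, before -2.57) and the macrophage median 2.67 (spread 0.321, before 2.46). Lymph node tissue is thus argued against as the whole cause of either change, with no error of these medians estimated. Macrophage markers were higher and endothelial markers lower. The macrophage median lay above the endothelial by 3.23 (spread 0.479, combined from the single-gene errors of both lists). A lower share of adipocytes that raises every other cell type alike would not give both directions. That comparison and its bound were set after the data had been seen, so it describes these 2 lists and is not a test. A gain of macrophages beside a loss of adipocytes stays open and was not tested. The 10 splits of these 6 libraries, with 4037 genes for the real 1 and 0 for the highest other, are too few for a share under 0.05. An effect of Raptor loss, which the design names, stays open and was not tested apart from cell content.

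Titles and treatment characteristics of the 6 WT libraries name opposite treatments. If the titles were right, the drug effect grouped by characteristics was predicted to correlate with that in KO at r below -0.2, and if the characteristics were right, above 0.2. The value was 0.0986 (SE 0.268), so the labels cannot be told apart by it. Btnl4, picked for its values, measured 13.6 to 21.7 CPM in the WT libraries whose characteristic says rosiglitazone, 0.25 to 0.65 CPM in the other WT libraries, 8.13 to 8.96 CPM in KO with the drug and at most 0.160 CPM in KO on diet. PPARG targets had medians of 1.26 in WT and 0.16 in KO, the latter -0.40 without KO on diet replicate 2 and 1.19 without replicate 1. Macrophage medians were -0.84 in WT and 0.53 in KO, the latter -0.03 without KO on diet replicate 2 and 1.45 without replicate 1, so neither list decides between the labels. Cell cycle medians went the other way, at -0.46 and 0.90. Of the genes called in WT, 393 of 578 had the same sign in KO. These were 315 of 418 among the higher and 78 of 160 (48.75%), near an even split, among the lower. Over all tested genes 52.57% had the same sign. Leaving out 1 library, r ranged from -0.127, without KO on diet replicate 2, to 0.221, without WT on diet replicate 2. On the TPM scale the KO medians of PPARG targets and macrophage markers were -0.41 and -0.11.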

How the results depend on the processing

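The covariates for marker levels, the fits without libraries rich in muscle or poor in B-cell markers, the fit to protein-coding genes, and the leave-one-out values and within-treatment permutations of Rptor were chosen after seeing the data; the other alternatives were planned. Counts are given as genes called for rosiglitazone in WT, rosiglitazone in KO, KO on diet, KO with rosiglitazone and the interaction. Their values above were 578, 4, 37, 4037 and 28. Counts not printed were within 1.5 times of these, save where they are said to be left out. Except where a construction is named, the cause was not tested.

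DESeq2 called 1981 genes for rosiglitazone in WT, 364 for rosiglitazone in KO, 736 for KO on diet and 531 for the interaction. Its calls held 569 of the 578, 4 of the 4, 37 of the 37, 4004 of the 4037 and 28 of the 28 genes. Limma-voom called 7325, 0, 6, 9182 and 61 in the order given, with 577, 0, 6, 4021 and 22 shared. With upper-quartile scaling the counts were 14 for rosiglitazone in KO, 77 for KO on diet and 44 for the interaction. Without a filter they were 20, 75 and 47 for the same contrasts, and with at least 1 CPM in 3 libraries 2 for rosiglitazone in KO and 44 for the interaction. With length offsets 330 genes were called for rosiglitazone in WT, 15 for KO on diet and 4 for the interaction. On the TPM scale 48, 254, 83 and 5 were called for rosiglitazone in WT, rosiglitazone in KO, KO on diet and the interaction; the median of all genes moved by -0.588 for rosiglitazone in KO, -0.354 for KO with rosiglitazone and -0.456 for the interaction. On that scale the list medians for rosiglitazone in KO turned for oxidative phosphorylation (-0.56) and macrophage markers (-0.11), and for PPARG targets, as given above. Fitting only the 2 groups compared gave 313, 0, 0 and 8461 for the first 4 contrasts, with a spread estimated from fewer samples by construction. Protein-coding genes alone gave 947, 11, 74 and 52 for all but KO with rosiglitazone, with fewer genes tested by construction.

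With the replicate block 1 gene was called for rosiglitazone in KO, 1 for KO on diet, 1 for the interaction, 430 for rosiglitazone in WT and 3444 for KO with rosiglitazone. Of 15 pairs of libraries with the same number, 6 correlated above 0.1 (from -0.419 to 0.608), and 6 of 11 libraries correlated best with their own number, so the numbers were not read as pairs. With WT grouped by titles 2886 genes were called for KO on diet, 624 for KO with rosiglitazone and 154 for the interaction, where the WT libraries trade places by construction.

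With the B-cell covariate 1999, 229, 1466 and 239 genes were called for all contrasts but KO with rosiglitazone. With the skeletal muscle covariate 198 were called for rosiglitazone in WT, 15 for KO on diet, 2650 for KO with rosiglitazone and 1 for the interaction. With the mature adipocyte covariate 1917, 596, 4256, 2522 and 556 were called. That covariate removes the adipocyte level by construction and turned the sign of 15 named values and of 1728 of the 4037 genes called in KO with rosiglitazone. There 475 of the 4037 stayed called, 383 with the same sign, and the balance went from 1476 higher and 2561 lower to 1842 and 680; for rosiglitazone in WT it went from 418 and 160 to 946 and 971. On diet these were Lep (0.51) and Plin1 (0.39). In KO with rosiglitazone they were Adipoq (0.31), Fabp4 (0.58), Plin1 (0.36), Lep (2.44), Pparg (1.39), Fasn (0.69), Pdhx (0.12), Sdha (0.0066), Robo4 (0.19), Cldn5 (0.38), Cd36 (2.38), Hbb-bt (0.26) and Hba-a2 (0.68). The oxidative phosphorylation median in KO with rosiglitazone was 0.52 with it. Without the 4 libraries richest in muscle edgeR called 0 genes in each contrast, with 958, 1045, 1492, 2538 and 750 at an unadjusted p under 0.05; 1 WT library with rosiglitazone was left and was assumed to vary like the other groups. Without the 3 libraries lowest in B-cell markers 5430, 902, 956, 7438 and 747 genes were called, and 29 gene lists in place of 19 for rosiglitazone in KO.

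Leaving out each library in turn, the counts ranged from 18 to 2779 for rosiglitazone in WT, 1 to 145 for rosiglitazone in KO, 2 to 250 for KO on diet, 1498 to 5919 for KO with rosiglitazone and 1 to 348 for the interaction. Gene lists called by camera ranged from 22 to 27 around 26 for rosiglitazone in WT, and from 22 to 27 around 23 for KO on diet. For KO with rosiglitazone they ranged from 22 to 26 around 23. For rosiglitazone in KO and the interaction camera called 19 and 23 lists with all libraries. Their ranges are left out, as they rest on fits with 1 KO library on diet. With an estimated correlation 0 lists were called in each contrast, and with the directional fry test 2 for rosiglitazone in WT, 0 for rosiglitazone in KO, 0 for KO on diet, 18 for KO with rosiglitazone and 0 for the interaction. The correlation of the drug effect between genotypes ranged from -0.127, without KO on diet replicate 2, to 0.221, without WT on diet replicate 2, around 0.0986. The ratio of Rptor between genotypes ranged from 0.737 to 0.829 in CPM and was 0.653 in TPM. With genotypes exchanged within a treatment it was 0.751 in CPM (exact p = 0.01) and 0.675 in TPM (exact p = 0.045), and the exact p in CPM was 0.095 with WT treatments from the titles. Over 169 pairs of a named gene and a contrast, and leaving aside WT grouped by titles, which reverses each fold change of rosiglitazone in WT by construction, 3568 of 4543 values kept their direction and side of the threshold, 742 lost the call, 218 gained it and 15 turned.

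On simulated counts with the depth and design of these libraries, 2-fold changes were recovered in at most 8.96% of cases and 4-fold changes of the interaction in 31.3%. Neither depth nor the number of samples was varied. Each simulated gene varied independently of the others, and changed genes were drawn from those above a set mean level. These rates therefore leave out errors from variation that many genes share.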

Other observations

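The tests of this part on the lists were planned; the genes in them follow the naming rule, and no test here was chosen after a result was seen.

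Further gene groups differed between KO and WT under rosiglitazone (3 libraries against 3, edgeR, WT labels by characteristic). Ribosomal protein genes rose in 30 of 55 cases over all genes and 45 adjusted over the list alone (median 0.70, adjusted p = 0.306 with an estimated correlation), with Rpl10a at 1.10 ± 0.22 and Rpl17 at 1.10 ± 0.23. On the TPM scale 0 of the 55 were called and the median was 0.12, beside a median of all genes moved by -0.354. Cholesterol synthesis had 10 of 25 members lower and 2 higher, 13 and 4 adjusted over the list alone (median -0.62, adjusted p = 0.397 with an estimated correlation), with Acat2 at -2.71 ± 0.29 and the squalene synthase Fdft1 at -2.08 ± 0.28. Erythrocyte markers fell in 5 of 7 cases, 6 adjusted over the list alone (median -1.98, adjusted p = 0.306 with an estimated correlation); Hbb-bt stood at -2.19 ± 0.48 and Hba-a2 at -2.08 ± 0.48, and haemoglobin genes are uncertain because paralogs share sequence. T and NK cell markers had a median of 2.06 in the same libraries.

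Amino acid response genes under ATF4, the transcription factor that mTORC1 also controls, went both ways: 4 of 25 rose and 6 fell, 5 and 9 adjusted over the list alone (median -0.57, adjusted p = 0.602 with an estimated correlation). Among them Aldh18a1 (1.11 ± 0.14) and Mthfd2 (1.21 ± 0.22) were higher in KO, and the serine synthesis gene Phgdh (-2.73 ± 0.44) and the stress sensor Sesn2 (-2.48 ± 0.37) were lower; on diet Sesn2 stood at -2.39 ± 0.43 (adjusted p = 0.0807). Inflammatory cytokines and chemokines had 3 of 27 members higher, 8 higher and 1 lower adjusted over the list alone (median 1.11, adjusted p = 0.316 with an estimated correlation), with the interleukin antagonist Il1rn at 4.10 ± 0.57 and Tgfb1 at 1.34 ± 0.20. Of 17 immediate early and heat shock genes 2 rose, Atf3 (3.87 ± 0.49) and Junb (1.32 ± 0.17), which were also the 2 adjusted over the list alone (median 0.35, adjusted p = 0.602 with an estimated correlation). Vegfb, an adipocyte-derived growth factor of the vasculature, stood at -2.09 ± 0.30.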
